A study of Mus musculus with 6 samples.

How the data were processed

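Gene expression was measured on 6 two-colour Agilent arrays of 1 design: CD24+ CD29-high mammary cells of Dll1-mCherry reporter mice sorted as mCherry-high or mCherry-low (1 array each), and F4/80+ macrophages from mammary glands of Dll1 conditional KO mice and wild type littermates (2 arrays each). Per the labels, all came from virgin females, each sample was labelled with Cy5, and universal mouse reference RNA, a mix of 11 mouse cell lines, with Cy3. The dyes were never swapped, so a dye bias of a probe stays in its ratio to the reference and cancels between arrays only where it is the same on each.

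Per the file headers, the scanner files were made with Agilent Feature Extraction 11.0.1.1 for the CD24+ CD29-high cells and 12.0.2.2 for the macrophages, while the submitters' processing notes give version 11.0 for all. Per the file headers, the spot and local background signals are unprocessed intensity values, and the processed signals are intensity values after background subtraction and dye normalization by the scanner software. Per the file headers, the log ratio column is the log10 of the processed sample signal over the reference signal. The authors' deposited value table holds log2 ratios of sample over reference: it followed the scanner log ratio with a slope of 1.00 to 1.01 and a correlation of 0.978 to 1.00 per array, with column medians of -0.117 to 0.139, not centred per gene. Of its probes, 79.1% to 97.3% per array lay within 0.01 of that ratio, and the step behind the others is not given in the sources used here.

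The design fixed before the data were examined assumed mean spot signals, but the macrophage files hold only median spot signals, so median signals were used on all arrays. Each array had 62976 spots, 3671 of them controls. Background was corrected with normexp (offset 50), log2 ratios were normalized by loess within each array (limma 3.58.1 and version 1.17.8 of data.table, in R 4.3.3), and spots marked by the scanner software as not uniform or as population outliers (170 to 500 per array) were left out. Spots were averaged to 55681 probes, 399 of them spotted 10 times. Probes were named by matching their accession to the reference table (27509 probes) or by the array design's own name (28172). The reference table served for names only, and probe coordinates were on mm9, per the file headers. A gene was represented by its probe of highest mean signal.

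Cy5 was well above background, by the scanner software, for 86.0% and 88.1% of spots in the Dll1-high and Dll1-low cells, for 63.5% and 47.4% in KO replicates 1 and 2, and for 71.9% and 50.9% in WT replicates 1 and 2. The median Cy5 signal was 330 and 352.5 over a background of 75 and 76 in the former, and 98 to 155.5 over 64 to 68 on the macrophage arrays. The 2 cell types were on different slides and scans, so cell type and slide cannot be told apart, and they were not compared gene by gene. On the macrophage slide, replicate 1 of both genotypes lay in the first row and replicate 2 in the second, so row and replicate number go together.

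Macrophage genes were tested where Cy5 was well above background on at least 2 of the 4 arrays, with limma's moderated t test and Benjamini-Hochberg adjustment at 0.05 (prior degrees of freedom 2.17). The gene p-values measure the spread between these samples, since the labels do not say whether they came from separate animals. The main fit has no term for the slide row, so a difference between rows enters that spread. Lists of genes were tested with camera at a preset correlation of 0.01, adjusted over the 42 lists. With this preset, camera's p-values treat the genes of a list as nearly independent and do not measure the spread between samples. Counts of members past the threshold were taken over all genes and adjusted over the list alone. The lists (cell type markers, Notch and Wnt genes, macrophage functions and general processes) were written before the data were examined. 5 of their 728 members were not on the array, and a list needed 4 measured members. For the CD24+ CD29-high cells, genes with Cy5 well above background on at least 1 of the 2 arrays were compared by their difference. A list was called apart where its median lay under percentile 2.5, or as far up on the other side, of 10000 random lists of the same size matched in 20 bins of mean signal. This describes the 2 arrays and is no test. A gene not well above background in one state was given as a lower bound, from the Cy5 channel after loess and quantile normalization of the mean signal, which stays open to dye bias.

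Genes were named by a rule fixed before the data were examined. For the macrophages it took the genes past the threshold, filled up to 12 in each direction with the smallest p among genes at least 2-fold apart whose KO arrays lay on the same side of both WT arrays. For the CD24+ CD29-high cells it took the 14 largest differences in each direction. It added Dll1, Notch and Wnt genes past the threshold or 2-fold apart, and up to 4 members of each described list. Names of clones, predicted genes and accessions were left out. Notch and Wnt genes given below 2-fold, and members named beyond these 4, were chosen after their values were seen.

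The scripts' statistics were tested on simulated data. With 24954 genes at the measured spread, 0 of 67 genes changed by 1, 0 of 67 changed by 2 and 0 of 66 changed by 4 on the log2 scale were called, with 0 false calls. At an SD of 0.1, 67 of 67, 67 of 67 and 66 of 66 were called, with 8 false calls among 24754 unchanged genes and 1 of 40 unshifted lists called. A list of genes shifted by 1 was called, with 0 of 40 unshifted lists called at the measured spread. For the CD24+ CD29-high cells (32083 genes) a list shifted by 0.3 lay apart, as did 3 of 40 unshifted lists. In both simulations genes varied independently and lists were random. In the macrophage simulation the arrays also varied independently, without a row difference shared by KO and WT. A fit with the replicate number as a block was not simulated. The counts of unshifted lists therefore do not measure false list calls where genes vary together. Alternatives tried were the scanner's processed signals, the authors' value table, quantile normalization, median centring, other filters, the mean of all probes, the Cy5 channel alone, all 6 arrays in one fit, other moderation and list tests, treat at 1.2-fold, the replicate number as a block, and leaving out each macrophage array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.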

Results

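Dll1, the gene behind the reporter and the knockout, was read first on each array. Its main probe, spotted 10 times, gave a log2 ratio over the reference RNA of 3.94 (SD over spots 0.168) in the Dll1-high CD24+ CD29-high cells and 3.26 (SD 0.11 over 9 spots) in the Dll1-low cells. On the F4/80+ macrophage arrays it read 0.80 (SD 0.188) and 2.25 (SD 0.203) for the conditional knockout (KO) and 0.78 (SD 0.143) and 3.24 (SD 0.162) for the wild type (WT), replicates 1 and 2 in that order. KO minus WT was -0.49 (SE 1.03, limma adjusted p 0.999), with 0.02 between the arrays in the first row of the slide and -0.99 between those in the second. It turned to 0.24 without KO replicate 1 and 0.74 without WT replicate 2, and was -1.21 without KO replicate 2 and -1.72 without WT replicate 1. The labels do not say which exons or which cells lose Dll1, so a probe outside the deleted part would check nothing. A second probe with a single spot stayed between -0.03 and 0.38 on the 6 arrays.

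Marker lists separated the cell types on 6 of 6 arrays. Basal keratin and contractile genes had a median log2 ratio of 3.49 and 3.41 in the Dll1-high and Dll1-low cells and 0.07 to 0.24 on the macrophage arrays. Macrophage genes (Csf1r, Adgre1, C1q and others) had medians of -0.34 and -0.22 in the CD24+ CD29-high cells, 3.17 and 3.16 in KO replicates 1 and 2, and 2.03 and 3.58 in WT replicates 1 and 2. WT replicate 1 thus had the lowest macrophage level of the 4 macrophage arrays, and it had the highest fibroblast level (0.46, against -0.35, -0.44 and -0.98 in KO replicate 1, KO replicate 2 and WT replicate 2).

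**Figure D1:**
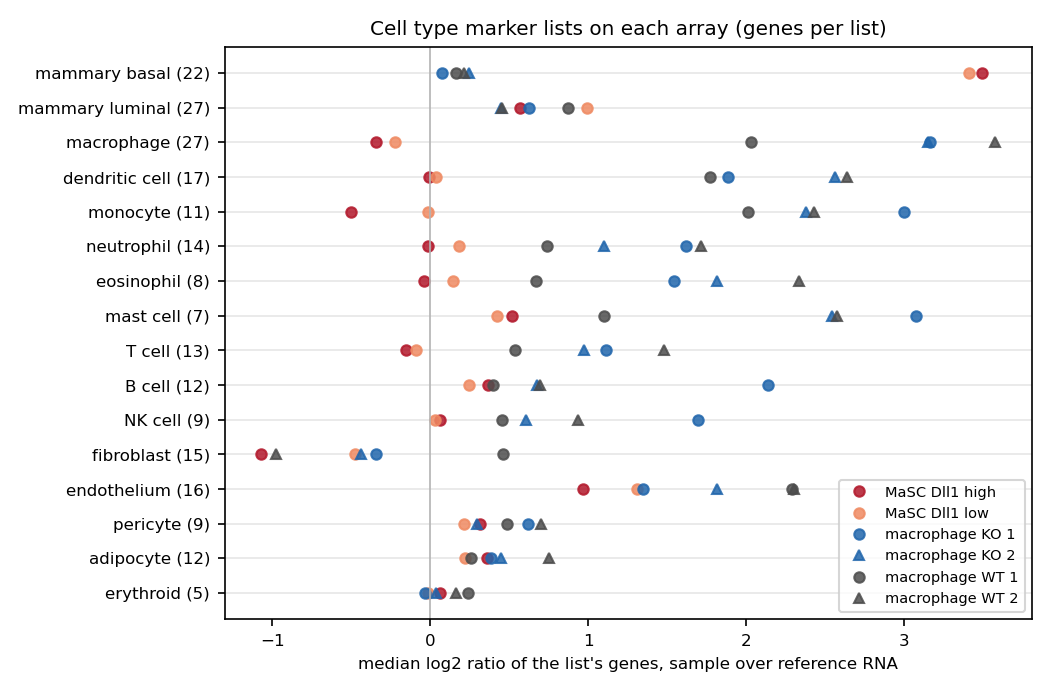
Median log2 ratio over the reference RNA of each cell type marker list on each of the 6 arrays.

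In the Dll1-high against the Dll1-low CD24+ CD29-high cells, Tspan8, a tetraspanin of mammary stem and progenitor cells, had the largest difference of any gene with a symbol (-2.55 on the log2 scale). The secreted Wnt inhibitor Sfrp1 (-1.71), the imprinted gene Mest (-1.62), the alveolar regulator Elf5 (-1.31) and the secretory genes Sbpl (-1.86), Dcpp3 (-1.48) and Dcpp1 (-1.29) were also lower in the Dll1-high cells. Higher there were the lipid droplet gene Plin4 (1.76), the dehydrogenase Adh1 (1.67), Pdk4 (1.45), which holds back glucose oxidation, and Cyp2f2 (1.21), while the lipid handling list was not apart (percentile 50.82). Also higher were the secreted factors Uts2b (1.63), Ereg (1.33), an EGF receptor ligand, and Ntf3 (1.203), and the protease inhibitor Cst6 (1.59). Of 32083 genes, 33 were at least 2-fold higher and 33 at least 2-fold lower, 0.206% in all. With the scanner's processed signals the counts were 333 and 664, and the authors' values gave 331 and 666. Each state has 1 array, so these differences have no replicate check and no p-value.

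The other genes of largest difference were, on the higher side, Calml3 (1.27), Ubd (1.27), Adamts17 (1.26), Grb14 (1.17) and Zfhx4 (1.17), and Saa2, whose signal was near background in the Dll1-low cells, so that it was at least 1.94-fold higher. On the lower side they were Acap1 (-1.52), the interferon-induced chemokine Cxcl10 (-1.40), Lyve1 (-1.36), Uggt1 (-1.35), Frmpd4 (-1.32), Trappc3 (-1.32) and the adhesion gene Nrcam (-1.31). For Calml3, Adamts17, Zfhx4, Mest, Uggt1, Cxcl10 and Dcpp1 another probe of the gene showed a smaller or no difference (Calml3 -0.07, Adamts17 0.20, Zfhx4 0.17, Mest -0.16, Uggt1 -0.13, Cxcl10 -0.36, Dcpp1 -0.04). The SD over spots of such a difference had a median of 0.124 and a 95th percentile of 0.247 over 367 probes spotted 10 times. Between replicate macrophage arrays, 3807 genes (KO) and 8344 genes (WT) were at least 2-fold apart, against the 66 here, a comparison not repeated with the processed signals or the value table. Across genotypes, KO and WT replicates 1 had 6884 such genes and replicates 2 only 226, so this yardstick varies widely between pairs, and Cy5 was weaker on both replicates 2.

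Dll1 itself was 0.68 higher in the Dll1-high cells (0.41 with the mean of its probes), rank 125 from the top, and 0.14 higher by its second probe. Of the other Notch ligands, Dll4 was lower (-0.42), while Jag1 (0.11) and Jag2 (0.21) were slightly higher. The 4 Notch receptors were lower by small amounts (Notch3 -0.40, Notch4 -0.32, Notch1 -0.23, Notch2 -0.07), with a list median of -0.28 at percentile 2.94 of 10000 matched random lists. Notch target genes (Hes1 0.06, Hey1 -0.22, Hes5 0.20) had a median of -0.03, percentile 54.1. Wnt ligands went both ways, with Wnt5b (0.58) and Wnt6 (0.53) higher and Wnt3 (-0.68), Wnt9a (-0.54) and Wnt5a (-0.46) lower, and a list median of -0.01 at percentile 67.8.

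Of 42 gene lists, 11 lay apart from random lists on the lower side in the Dll1-high cells. Luminal genes were lower for 22 of 27 (median -0.22, percentile 0.05), led by Elf5, Csn3 (-0.51), Esr1 (-0.43) and Ly6a (-0.41). Fibroblast genes were lower for 13 of 16 (median -0.57, percentile 0): Fn1 (-1.03), Pi16 (-0.96), Col1a1 (-0.72) and Col1a2 (-0.69). Interferon response genes were lower for 19 of 25 (median -0.24, percentile 0.01): Cxcl10, Rsad2 (-0.79), Oasl1 (-0.76) and Ifit1 (-0.76). Monocyte genes (Nr4a1 -0.83, Ms4a4c -0.62; 8 of 10 lower, median -0.47, percentile 0) and inflammatory macrophage genes (Cxcl10, Cxcl11 -0.69; 20 of 23 lower, median -0.22, percentile 0.08) lay on the same side. So did the epithelial-mesenchymal (Fn1, Cldn7 -0.79; median -0.32, percentile 0), endothelial (Flt1 -0.62; -0.22, percentile 0.27), alternative macrophage (Pdcd1lg2 -0.38; -0.19, percentile 0.29), lysosomal (Ctsk -0.63; -0.17, percentile 1.00), complement (C4b -0.72; -0.21, percentile 1.12) and immediate early (Nr4a1; -0.17, percentile 1.17) lists. The epithelial-mesenchymal list (14 of 18 lower) pools epithelial genes (Cldn7, Ocln -0.43) with mesenchymal genes (Fn1, Vim -0.54). Its median therefore gives no direction between the 2 states. The probes of Cxcl11 and Ms4a4c had mean log2 signals of 17.36 and 15.97, near those of ribosomal protein probes (Rps2 16.25). Mgl2 (15.79) of the alternative macrophage list was similarly bright, as were Siglech (16.67), Csf3r (15.91) and Itgam (15.44) of lists not apart. These probes may therefore not read the named genes. The lysosomal list was no longer apart with the processed signals (percentile 3.41) and the authors' values (3.42), nor the alternative macrophage list under median centring (5.84). Markers of fibroblasts, monocytes and endothelium thus moved with the interferon and inflammatory genes, and a change in the cells sorted cannot be separated from a change within cells here.

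On the higher side, genes of oxidative phosphorylation were higher for 19 of 22 by small amounts (median 0.09, percentile 99.7), with Sdhb (0.25), Atp5o (0.23) and Cox6c (0.21) at the top. The extracellular matrix list (median 0.10, percentile 99.8) was split and its mean was -0.01: Fn1, Col1a1 and Col1a2 were lower, while Col5a2 (0.59), Thbs1 (0.53), Col7a1 (0.44) and Col4a2 (0.43) were higher. The mammary stem cell list was at the bound (median 0.06, percentile 97.55, draw error 0.155), with a mean of -0.09 on the other side of 0, and was no longer apart in 7 of 10 alternatives: Tspan8, Procr (-0.68) and Cd1d1 (-0.49) were lower and Dll1 and Itgb3 (0.48) higher. The cells were sorted on the Dll1 reporter, so the rise of Dll1 in this list is no support for it. Wnt target genes lay at percentile 97.46 (draw error 0.157) with a median of 0.08 and a mean of -0.01, Nkd1 (0.73) being the highest. Basal genes were not apart (median 0.06, percentile 96.1), with Tagln (1.16) and Myl9 (0.67) higher and Procr and Vim (-0.54) lower. Of genes that recruit macrophages, Csf3 (0.71) and Il34 (0.70), a ligand of Csf1r, were higher and Cxcl12 (-0.43) and Ccl5 (-0.42) lower, with a list median of -0.10 at percentile 11.4. In the growth factor list (median -0.07, percentile 21.1), Bmp2 (-1.25) and Id3 (-0.62), a target of BMP signalling, were lower.

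**Figure D2:**
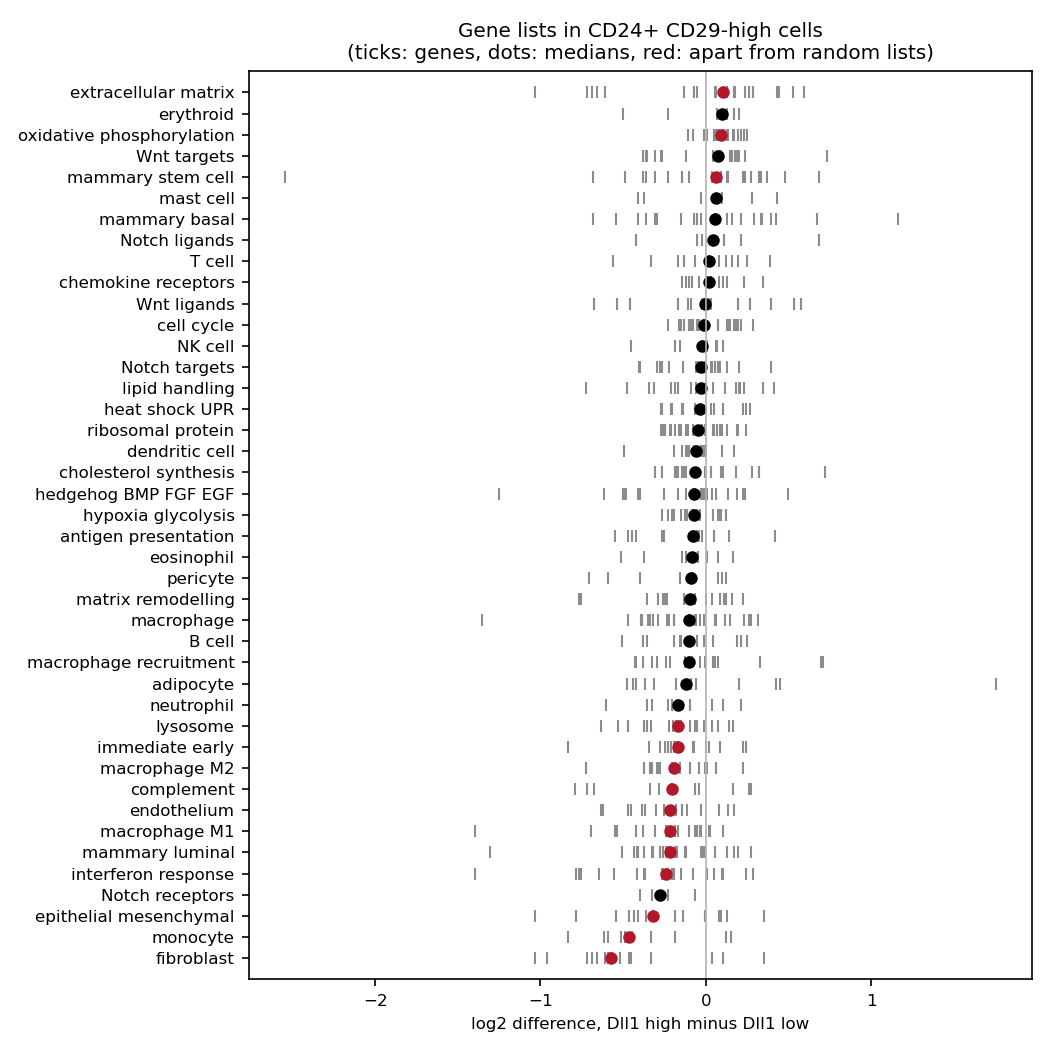
Difference between Dll1-high and Dll1-low cells for each gene list, with 1 array per state. Ticks are genes, dots are medians, and red dots lie apart from matched random lists.

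In the macrophages, Cdh5, the adhesion molecule of endothelial junctions, had the smallest p among the named genes and was lower in KO (-2.12, SE 0.42; -1.996 and -2.238 within the first and second slide rows). Other endothelial genes among the named genes were also lower: Esam (-1.49, SE 0.40), Ptprb (-1.22, SE 0.31) and Nos3 (-1.35, SE 0.41). With the scanner's processed signals and with the authors' value table Cdh5 shrank to -0.55, Ptprb to -0.55 and Nos3 to -1.125, and Esam turned to 0.14. The fibrinogen chains Fgb (-2.37, SE 0.69) and Fgg (-1.49, SE 0.41, and -0.16 with those signals and that table), the growth factor Ptn (-2.07, SE 0.41) and the dynein gene Dnah6 (-2.08, SE 0.44) were lower as well. Higher in KO were Actl11 (3.22, SE 0.73), the leukocyte receptor Lilr4b (1.67, SE 0.64), the lymphoid regulator Ikzf1 (1.22, SE 0.50), the endolysosomal exonuclease Pld4 (1.15, SE 0.46) and Fermt3 (1.06, SE 0.48), which activates leukocyte integrins. No gene passed: with limma, 0 of 24954 genes had an adjusted p under the threshold of 0.05 (the smallest was 0.999). An unadjusted p under it was seen for 31 genes (0.124%), well below the share of 0.05 for unchanged genes if the model held. The difference between slide rows enters the spread of this fit and can raise its p-values. With the replicate number as a block 140 genes had an unadjusted p under it and 0 passed. A robust fit with a trend gave 0 and 62, and treat gave 0 and 22. These genes are therefore values and not changes.

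The other named genes were Spg21 (1.21, SE 0.34), Zfp871 (1.08, SE 0.40), Gnpnat1 (1.49, SE 0.56), Rbm7 (1.09, SE 0.44), Lig3 (1.39, SE 0.57), Ckap2l (1.40, SE 0.63) and Nyap2 (1.08, SE 0.49) on the higher side, and Csgalnact1 (-1.49, SE 0.42), Pakap (-1.19, SE 0.34), Srsf11 (-1.63, SE 0.50) and Wfdc2 (-1.12, SE 0.34) on the lower side. Of these, Wfdc2 turned to 1.27 with the scanner's processed signals and with the authors' value table, Pakap to 0.027 under median centring, and Spg21 (-0.16) and Lig3 (-0.12) in the Cy5 channel alone. Srsf11 shrank to -0.08 under median centring and grew to -3.20 in the Cy5 channel alone. Ckap2l shrank to 0.015 in the Cy5 channel alone and Gnpnat1 to 0.29 without KO replicate 1. Other probes of Gnpnat1, Lig3, Ikzf1, Nyap2, Pakap and Nos3 showed little difference (Gnpnat1 0.00, Lig3 0.13, Ikzf1 0.07, Nyap2 0.08, Pakap -0.10, Nos3 -0.14), and those of Ptn (-0.57), Ptprb (-0.54) and Wfdc2 (-0.37) a smaller one. Both KO arrays lay on one side of both WT arrays for 5026 genes (20.1%, where chance gives 33.3%). Of these, 172 were at least 2-fold higher and 261 at least 2-fold lower in KO. In data simulated with the measured spread, 0 of 66 genes changed by 4 on the log2 scale were called, so the count of 0 does not exclude large changes.

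Endothelial genes as a group were lower in KO: 15 of 16 were lower and 13 were lower within both slide rows (median -0.63; -0.82 and -0.59 in the first and second rows; camera adjusted p 2.2e-05 with the preset correlation). With an estimated correlation camera gave an adjusted p of 0.867, and fry gave 0.949, so the call was lost in both. Under median centring, which moved the median of all genes from -0.09 to 0.46, the endothelial median was -0.01 and the list passed (adjusted p 0.00038). Cdh5, Esam, Egfl7 (-1.10, SE 0.87) and Plvap (-0.89, SE 0.47) differed most, and 0 of 16 passed over all genes or adjusted over the list alone. When an array was left out, the median was -0.92 without WT replicate 1 and -0.47 without WT replicate 2. It was -0.31 without KO replicate 1 and -0.89 without KO replicate 2. The list no longer passed without WT replicate 2. Each of these fits leaves 1 array in a genotype, so its p-value does not measure the spread there.

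**Figure D3:**
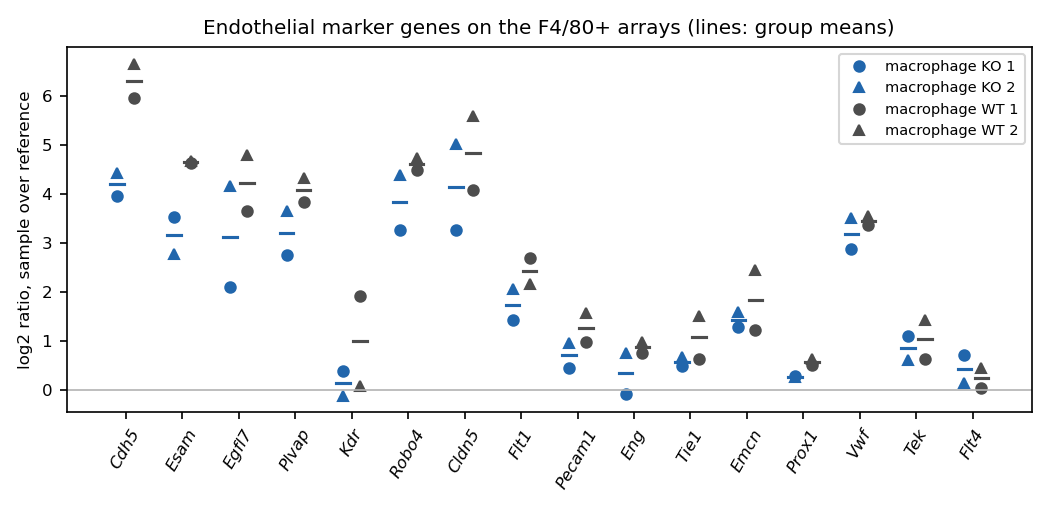
Log2 ratio over the reference RNA of the endothelial marker genes on the 4 macrophage arrays, with group means as lines.

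The next 6 lists passed with camera's preset correlation, and each was lost with an estimated correlation (adjusted p 0.867) and with fry (0.949). Macrophage identity genes were higher in KO for 21 of 25 (median 0.51; 0.50 and 0.33 in the first and second rows; camera adjusted p 2.2e-05): Lyz2 (1.84, SE 1.14), C1qa (1.57, SE 1.01) and Adgre1 (1.44, SE 0.81), the gene of F4/80, were higher and Lyve1 (-1.57, SE 2.77) lower. Inflammatory macrophage genes were higher for 17 of 22 (median 0.48, adjusted p 4.9e-04), with Tnf (1.47, SE 0.93), Cxcl10 (1.203, SE 0.88), Ptgs2 (1.13, SE 0.69) and Ccl4 (1.05, SE 1.01) at the top. Antigen presentation genes were higher for 10 of 13 (median 0.34, adjusted p 0.021), with H2-Aa (1.37, SE 0.80) and H2-DMa (1.14, SE 0.78). Markers of B cells (Iglv1 1.15, against Jchain -1.28; median 0.71, adjusted p 9.7e-04), NK cells (Gzma 1.93; 0.65; 9.9e-04) and mast cells (Hdc 1.46, against Tpsb2 -2.18; 1.06; 0.0038) moved with them. In the second row alone the medians of these last 5 lists were near 0 (0.09, 0.05, 0.01, 0.03 and -0.04, in that order), against 0.71, 0.65, 1.39, 1.17 and 2.14 in the first. Antigen presentation no longer passed with the processed signals (adjusted p 0.135), the authors' value table (0.22) or the mean of all probes (0.059), and NK and mast cells no longer passed under median centring. Without WT replicate 1 none of the 6 passed: the macrophage median was -0.14 (adjusted p 0.899), the inflammatory -0.20 (0.615), antigen presentation 0.04 (0.653), B cells 0.25 (0.0895), NK cells 0.36 (0.165) and mast cells 0.27 (0.314). Without KO replicate 2 the macrophage (0.07, 0.506), inflammatory (0.15, 0.46) and antigen presentation (0.64, 0.154) lists did not pass, and without KO replicate 1 antigen presentation (0.50, 0.0644), B cells (0.47, 0.165), NK cells (0.19, 0.206) and mast cells (1.04, 0.124) did not. Without WT replicate 2 all 6 passed, with medians of 0.92 (NK cells) to 2.48 (mast cells).

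Genes of the cell cycle, matrix and glycolysis were lower in KO in the first slide row (medians -0.99, -1.14 and -1.08) and near 0 in the second (-0.01, 0.04 and 0.03). These 3 lists passed with camera's preset correlation, and each was lost with an estimated correlation (adjusted p 0.867) and with fry (0.949). Cell cycle genes were lower for 20 of 23 (median -0.55; camera adjusted p 7.0e-04), led by Tyms (-0.94, SE 0.73), Ccne1 (-0.92, SE 0.58) and Mcm5 (-0.85, SE 0.57). Extracellular matrix genes were lower for 18 of 21 (median -0.74, 0.0027), with Sparc (-1.41, SE 0.66) and Col1a2 (-1.10, SE 1.17) lower and Thbs1 (1.2, SE 0.84) higher. Hypoxia and glycolysis genes were lower for 17 of 19 (median -0.50, 0.0030), with Pgk1 (-1.13, SE 0.79) and Bnip3 (-0.90, SE 0.66) lower and Egln3 (1.02, SE 1.45) higher. Fibroblast markers moved with them without passing (Mfap5 -1.12; median -0.55, 0.0847), at -1.60 in the first slide row and 0.31 in the second. The 3 lists were also lost without WT replicate 1 (adjusted p 0.897, 0.897 and 0.822, medians -0.08, -0.13 and -0.06). Without KO replicate 1 the matrix list did not pass either (median -0.57, adjusted p 0.167), and without WT replicate 2 the medians were -0.99, -1.23 and -0.78. Under median centring, with a median of all genes of 0.46, the medians were 0.60, 0.39 and 0.54 and the lists did not pass (adjusted p 0.083, 0.658 and 0.144). In the Cy5 channel alone the matrix (median -0.34, adjusted p 0.055) and hypoxia and glycolysis (-0.12, 0.12) lists did not pass.

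**Figure D4:**
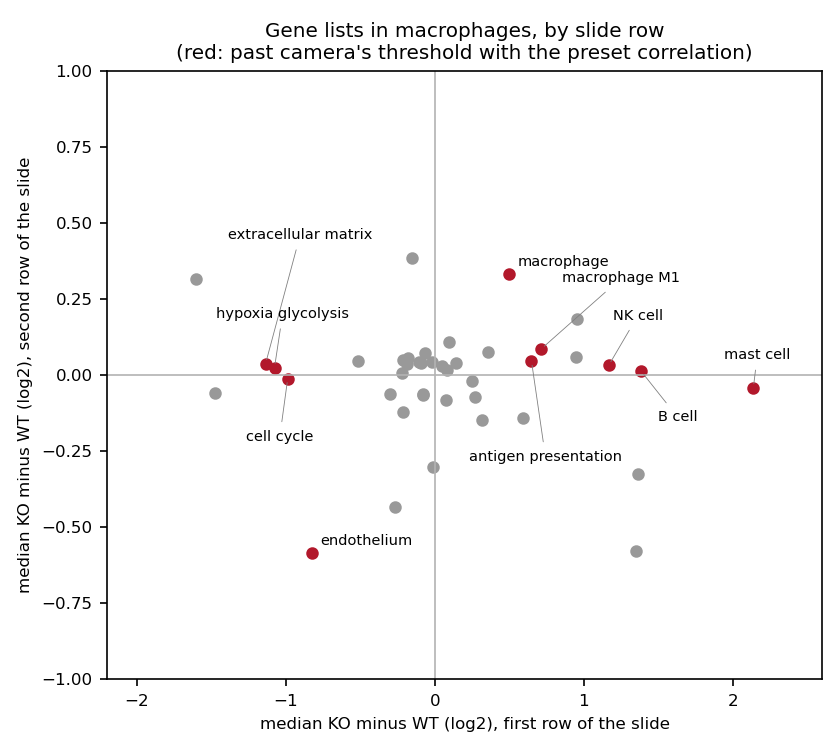
Median KO minus WT difference of each gene list within the first and the second row of the slide. Of the lists past the threshold (red), the endothelial and macrophage lists lay furthest from 0 in the second row.

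Notch and Wnt genes of the macrophages passed no test. Of the ligands, Wnt10a was lower in KO (-1.70, SE 0.79; -2.92 and -0.48 in the first and second rows), as were Wnt16 (-1.71, SE 1.40; -3.26 and -0.17), Dlk1 (-1.23, SE 0.68; -2.004 and -0.459) and Wnt5a (-1.23, SE 0.98; -2.57 and 0.12), so that most of each difference came from the first row. The Wnt ligand list had a median of -0.63 (camera adjusted p 0.236). Notch1 (0.11, SE 0.55), Notch2 (0.49, SE 0.51), Notch3 (-0.59, SE 0.41) and Notch4 (-0.27, SE 0.39) went both ways (list median -0.08, 0.963), and so did Notch ligands (Jag1 0.02, SE 0.51; list median -0.07, 0.880), Notch targets (median -0.02, 0.981) and Wnt targets (median 0.07, 0.830). The 4 arrays allow 3 splits, so the smallest exact permutation p is 0.333 and cannot reach the threshold.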

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

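Mean spot signals, other random draws and the marker levels under other signals were chosen as checks after the data were seen. The count of 0 macrophage genes past the threshold was the same in all 16 alternatives, with 22 to 140 genes at an unadjusted p under it, and 6 to 4517 when an array was left out (the highest without WT replicate 2). A fit in which a genotype keeps 1 array assumes that it varies like the other. In data simulated at the measured spread, 0 of 66 genes changed by 4 on the log2 scale were called. The repeated count of 0 therefore says little about robustness.

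The number of macrophage lists past the threshold, 10, became 16 under median centring, 3 to 17 when an array was left out (3 without WT replicate 1, 17 without WT replicate 2), 0 with an estimated correlation and 0 with fry. Median centring raised the median of all genes from -0.09 to 0.46. With it the medians changed sign for the cell cycle (0.60), extracellular matrix (0.39) and hypoxia and glycolysis (0.54) lists, which lie near that shift, and the endothelial median was -0.01. Inflammatory macrophage genes ranged from -0.20 (without WT replicate 1) to 1.14 (without WT replicate 2) when an array was left out, and had a median of 1.15 under median centring. Over all list alternatives, 112 kept their call, 43 kept the direction only and 5 changed sign: these 3, with the shift of all genes, and the macrophage (-0.14, up to 0.94 without another array) and inflammatory lists without WT replicate 1.

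Of the named macrophage genes, Esam (0.14) and Wfdc2 (1.27) turned with the scanner's processed signals and with the authors' value table, Pakap (0.027) under median centring, and Spg21 (-0.16) and Lig3 (-0.12) in the Cy5 channel alone. The cause was not tested. Dll1 turned without KO replicate 1 (0.24) and without WT replicate 2 (0.74). In the other 384 alternatives the direction and call stayed the same, but sizes did not. Cdh5 shrank from -2.12 to -0.55 and Fgg from -1.49 to -0.16 with the processed signals and the value table. Many of the 384 could not differ. Quantile normalization, the replicate block, the fit of all 6 arrays, the robust fit with a trend and treat gave each named gene the difference of the main fit. With 0 genes called in the main fit, a call could change only by a gene passing. Replicate numbers are shared, but the labels do not pair them. With the replicate block 0 genes passed (140 at an unadjusted p under the threshold) and 14 lists did. The deviations of same-numbered arrays correlated at 0.593. The slide and scan could not be fitted as a block, since the macrophage arrays share 1 slide and scan.

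In the CD24+ CD29-high cells, 997 genes were 2-fold apart with the scanner's processed signals (333 higher, 664 lower) and 997 with the authors' value table (331 higher, 666 lower), against 33 and 33. They were dim (median mean signal 6.79, against 8.76 for all genes), and 61 of the 66 were among them in each. At a difference of 1.5, 9 genes remained. Other settings gave 47 to 68. Named genes kept their direction, but moved by more than the median SD over spots in 57 alternatives and by less in 174 (Frmpd4 from -1.32 to -4.08 and Elf5 from -1.31 to -3.20 with the processed signals, Cxcl10 from -1.40 to -0.88 with the mean of all probes). Lists apart numbered 13 to 16, and 10 calls were lost, 7 of them of the mammary stem cell list. Marker lists told the cell types apart on 6 of 6 arrays with each of the 4 other signals and normalizations tried for them.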

Other observations

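The explanations in this part and the tests of them were chosen after the results were seen. Some of the values used, such as those under median centring, came from alternatives planned before.

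WT replicate 1 stood apart from WT replicate 2: 8344 genes (29.7%) were at least 2-fold apart, against 226 (1.05%) between KO replicate 2 and WT replicate 2. Over probes, WT replicate 1 correlated at 0.42 with WT replicate 2, 0.44 with KO replicate 2 and 0.68 with KO replicate 1. With the Dll1-low and Dll1-high CD24+ CD29-high arrays it correlated at 0.59 and 0.52, and KO replicate 1 did so at 0.57 and 0.52. KO replicate 2 and WT replicate 2 correlated at 0.94. The CD24+ CD29-high cells were on another slide, so these values do not settle what the sample held. If macrophages alone were fewer, the markers of all other cell types would rise alike. Of 14 such lists 3 were lower on WT replicate 1 by over 2 SE (neutrophil -1.32, eosinophil -1.50, adipocyte -0.64) and 2 were higher (fibroblast 1.52, basal 0.64). These SEs are over the genes of a list, taken as independent, and not over samples. The adipocyte difference was -0.73 between the KO arrays, so it was not particular to WT replicate 1. These values argue only against a uniform rise of the other cell types. A lower share of macrophages with more cells of some other types, such as fibroblasts, stays open, since the test cannot exclude it. Weak Cy5 signal pulling ratios towards 0 would spare bright genes. Of the 6243 genes brightest in Cy5 on both WT arrays, 34.9% (binomial SE over genes 0.603) were at least 2-fold apart. Among all tested genes 32.9% were, which argues against weak signal as the whole cause. A shift shared by the first row of the slide may account for part of the pattern over all genes, since the differences between the rows in KO and in WT correlated at 0.593. The fibroblast genes differed by 1.52 between the WT arrays and by -0.17 between the KO arrays. The gap was 1.70 (SE 0.248 over genes), so an equal shift in both genotypes would not account for these values. With 1 array per row and genotype, the spread between samples is not known. Row, collection and replicate number cannot be separated, and no biological explanation was tested.

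Endothelial genes were lower on both KO arrays. WT replicate 1 alone is argued against, since the list passed without it (camera adjusted p 8.2e-09, against a range up to 0.949 over the alternatives). Fewer endothelial cells among the F4/80+ cells of the KO mice cannot be told apart from a change within cells: the count of 15 of 16 markers lower restates the pattern and supports neither. The F4/80 sort is meant to remove such cells. Under median centring the median was -0.01, against 0.46 for all genes, and the list passed (adjusted p 0.00038). The 3 splits of the 4 arrays are too few to exclude chance: KO against WT gave 10 lists and the highest other split 12, so 2 of the 3 splits gave as many. The split by slide row gave 4541 genes at an unadjusted p under the threshold against 31 for the genotypes, though 0 passed after adjustment (smallest adjusted p 0.0942), which points to a structure of the samples. KO and WT were 2-fold apart for 226 genes in the second row and 6884 (24.1%) in the first. In the second row Cy5 was weaker (47.4% and 50.9% of spots well above background, against 63.5% and 71.9%). The log ratios there were also narrower (SD 0.754 and 0.786, against 0.921 and 1.07), which can lower the count. KO and WT correlated at 0.964 in the second row (SD of their difference 0.294) and at 0.693 in the first (0.97). How much of the gap weaker signal accounts for was not tested. Within the first and second rows the endothelial medians were -0.82 and -0.59.

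Fibroblast genes were lower in the Dll1-high cells. Background correction or normalization is argued against, since the weakest median over the other signals and normalizations was -0.48, against -0.57. Fewer fibroblasts among the sorted cells cannot be told apart from a change within cells: the count of 13 of 16 markers lower restates the pattern and supports neither, and the CD24+ CD29-high gate is meant to remove fibroblasts. Dcn (0.04), Col5a1 (0.10) and Postn (0.35) were not lower, and 8 of the markers are in another list. With 1 array per state the pattern was not repeated.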
